A study of Mus musculus with 8 samples.

How the data were processed

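Donor B1-8hi B cells were sequenced as 8 RNA libraries in 4 groups of 2: light zone (LZ) and dark zone (DZ) germinal centre B cells, each either Prdm1-deficient (sKO) or Bach2- and Prdm1-deficient (dKO). Per the labels' protocols, the naive donor cells were given to wild-type recipients, tamoxifen (3 mg for 3 days) deleted the floxed genes, and NP-specific donor cells negative for CD38 were sorted on day 10 after immunization from pooled spleens of 5 recipients. RNA of about 30000 cells per library was made into libraries with the NEBNext Ultra RNA kit and sequenced on an Illumina instrument, per the labels. The kit is not stated to keep the strand, so overlapping genes can share reads.

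The file analysed was 1 table of FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments) for 23234 gene symbols and 8 columns, per the file headers. TopHat2 2.0.8, Cufflinks 2.1.1 and the mm9 genome are named in the submitters' processing notes, with no role, order, options or gene annotation. A row of library codes was left out, and 0 columns were unmatched to a sample. Counts were not analysed here, so the tests for counts planned as an alternative were not run. No coordinates are given.

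Values were taken as log2(FPKM + 1), and genes with at least 1 FPKM in at least 2 libraries were tested (10610 genes). Fits were made with limma 3.58.1 in R 4.3.3, as group means with an intensity trend in the variance, 4 residual and 2.46 prior degrees of freedom, and all 8 libraries in 1 fit. The contrasts were dKO against sKO in LZ, in DZ and in the mean of both zones, LZ against DZ in sKO and in dKO, and the difference of the genotype effects between zones (the interaction). Tests were 2-sided, with Benjamini-Hochberg adjustment within each contrast and a threshold of an adjusted p of 0.05; rose and fell are used for genes past it.

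In all, 30 gene lists were written before the data were examined: the targeted genes, mTORC1 and ATF4 amino acid supply, glycolysis, cholesterol synthesis, oxidative phosphorylation (the respiratory chain), MYC targets and ribosome biogenesis, cytosolic ribosomal proteins, memory, germinal centre identity, plasma cell, light zone, dark zone, NF-kB and CD40 response, antigen receptor response, AP-1 and MAF factors, heme and oxidative stress, BCL2 family pro-survival and pro-apoptotic genes, survival receptors, quiescence, G1/S, interferon, heat shock, immunoglobulin constant genes, and markers of T, myeloid, erythroid, NK, stromal, and naive or marginal zone B cells. Lists with at least 3 tested members were tested with camera (preset correlation 0.01), again with a correlation between genes estimated from the data, and with fry. The preset assumes nearly independent genes, and the estimated form is the stricter one. It was stricter on simulated independent genes too. There the MYC list, shifted by 0.3 in dKO, had adjusted p = 2.02e-41 by camera in LZ with the preset. With the estimated correlation it had adjusted p = 0.00219 by camera. A call lost with the estimated form thus does not by itself show that correlation between genes made the call. Members past the threshold were counted over all genes tested and adjusted over the list alone.

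Genes were named by a rule also set before the data were examined: among genes past the threshold with at least 5 FPKM in the higher group and no overlap between the libraries of the groups, leaving out microRNA and small nucleolar RNA genes, unnamed gene models and antigen receptor segments, the 10 largest changes in each direction in each zone's genotype contrast, 8 in the zone contrast of sKO and 5 in the others; list examples came from the 4 members with the smallest p. Bach2, Prdm1, Cd86, Cxcr4, Bcl6, Irf4, Bcl2, Myc, Ccr6, S1pr2, Slc7a5 and Bcl2l11 were among the genes to be given in any case. Some genes that the rules named are not reported here. Actr3, Klf2, Rgs13, S100a8 in the LZ genotype contrast, the 3 microRNA genes and the genes that differed between sKO replicates were named after their values were seen.

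The alternatives were a replicate block, other pseudocounts, filters, scalings and variance priors, only the libraries compared, and leaving out each library in turn. After the data were seen, fits without small RNA genes and without both sKO replicate 1 libraries were added. Relative depth came from the commonest ratio between libraries of values from 0.001 to 0.1 FPKM, a ratio shared by 20.2% to 28.1% of such genes. The fits were tested on simulated data for 10610 genes: at true changes of 0.3, 0.5, 1 and 2, 12%, 60%, 100% and 100% of the changed genes were recovered in the LZ genotype contrast (5 of 141 calls false), and 24%, 66%, 96% and 100% in DZ (7 of 150 false). Changes under 0.5 were thus often missed in the simulation. It changed only 50 genes at each size, while 3299 and 1258 genes were called in the LZ and DZ data. The adjusted threshold depends on how many genes change, so these shares need not hold for the data. Figures used Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.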

Results

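RNA from donor germinal centre B cells of the mouse spleen was sequenced. Germinal centre B cells are activated B cells that mutate and select their antigen receptors, and they cycle between a dark zone (DZ), where they divide, and a light zone (LZ), where they are selected. The donor cells carried the B1-8hi antigen receptor, which binds NP, and were sorted on day 10 after immunization as NP-binding LZ (CD86 high, CXCR4 low) or DZ (CD86 low, CXCR4 high) cells. They lacked either Prdm1 (also called Blimp1, the plasma cell factor; sKO here) or both Prdm1 and Bach2, a transcriptional repressor of the B cell lineage (dKO here), according to the labels. Each of the 4 groups, sKO LZ, dKO LZ, sKO DZ and dKO DZ, had 2 libraries, and no group with intact Prdm1 was analysed here.

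Levels are given as FPKM (mean ± SD, n = 2), and changes as differences on the log2(FPKM + 1) scale ± SE, which understates the change of low genes. Genes ranked by change had at least 5 FPKM in the higher group and no overlap between the libraries compared. MicroRNA and small nucleolar RNA genes, unnamed gene models and antigen receptor segments were left out of the ranking, and some microRNA genes changed more than the genes named. Counts of 2 or fewer genes of a list in the same direction moved by at most 2 genes when 1 library was left out, unless a range is given. FPKM summed to 502214 to 540885 per library over 23234 genes, of which 10192 to 10250 reached 1 FPKM in each library. Absolute depth is unknown from FPKM; judged from the smallest steps of low values, the DZ libraries were on average 1.43 times as deep as the LZ libraries, and dKO relative to sKO depth was 1.05 in LZ and 0.971 in DZ. Replicates correlated at 0.946 to 0.960 (Pearson, log2 scale, across genes). An exact 0 in these values can be a failed estimate: Actr3, an actin nucleation subunit, was listed at 0 in sKO LZ replicate 2 and at 417 to 550 FPKM in the other libraries. The labels do not say whether replicates are separate pools of mice, so the p-values measure only the spread between these libraries.

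Bach2 transcripts were present in every library, at 51.6 ± 2.49 FPKM in sKO LZ, 63.6 ± 1.27 in dKO LZ, 75.4 ± 1.08 in sKO DZ and 95.3 ± 1.25 in dKO DZ. The gene thus rose in the libraries labelled double-deficient, by 0.30 ± 0.044 in LZ (adjusted p = 0.00454, limma) and 0.34 ± 0.044 in DZ (adjusted p = 0.00894, limma; 0.0763 without dKO DZ replicate 1 and 0.0679 without replicate 2). A gene-level FPKM also counts the exons that the deletion leaves in place, and the deleted exon was not given in the sources used here, so this value checks nothing about the labels and dKO stands for the label throughout. Prdm1, floxed in every library, was below the filter on low values, at 0.0380 ± 0.0278 FPKM in sKO LZ, 0.973 ± 0.00925 in dKO LZ, 0.0848 ± 0.0529 in sKO DZ and 0.346 ± 0.125 in dKO DZ, and Bcl2, the founding anti-apoptotic gene of its family, was at 0.635 ± 0.0308, 0.611 ± 0.0932, 0.222 ± 0.0311 and 0.162 ± 0.00253 in the same order.

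In LZ cells the largest rise in dKO over sKO among the genes ranked was in Mgll, which encodes monoacylglycerol lipase, from 2.92 ± 0.282 FPKM in sKO to 14.3 ± 0.971 in dKO (1.97 ± 0.095). The anti-inflammatory cytokine gene Il10 went from 0.935 ± 0.506 to 6.39 ± 0.944 (1.95 ± 0.20). The sialyltransferase gene St3gal6 went from 9.76 ± 0.0677 to 34.4 ± 0.514 (1.72 ± 0.048). Palm (paralemmin), the adhesion gene Alcam, the phosphatase gene Ptpn22, which restrains antigen receptor signalling, Btnl3 and Mettl7a1 rose by 1.24 to 1.39 (adjusted p 0.000117 to 0.00211 over these 8 genes, limma). Serpinb1a, a serine protease inhibitor, fell from 6.01 ± 1.46 to 1.09 ± 0.0467 (-1.73 ± 0.19). The actin-capping gene Capg fell from 11.8 ± 1.31 to 3.80 ± 0.745 (-1.42 ± 0.18). The interferon-inducible GTPase gene Gbp2 fell from 6.88 ± 0.481 to 1.98 ± 0.232 (-1.40 ± 0.11). Pdcd4, an inhibitor of translation initiation, fell from 19.5 ± 1.04 to 7.13 ± 0.0722 (-1.33 ± 0.097). Rab37, Grm6, the lysophosphatidylserine receptor gene Gpr174, Mxd4, whose product competes with MYC for MAX, Trim7 and Mndal changed by -1.31 to -1.07 (adjusted p 0.000884 to 0.00271 over the 10 lower genes, limma). In each of these genes both libraries of the higher group lay above both of the lower group, which the ranking required.

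A further pair of genes with large changes in LZ are uncertain. Rpl26, a ribosomal protein gene with near-identical pseudogenes that can share its reads, was at 4.61 and 9.25 FPKM in the sKO libraries and 35.6 and 13.8 in the dKO libraries (1.62 ± 0.47, adjusted p = 0.0415, limma). Tyrobp, an adaptor of myeloid and NK cell receptors, was at 1.31 and 2.26 against 3.58 and 11.2 (1.45 ± 0.44, adjusted p = 0.0493). The Rpl26 call was lost without sKO LZ replicate 1 (0.159), dKO LZ replicate 1 (0.15) or any DZ library (up to 0.0695). The Tyrobp call was lost without any library except dKO LZ replicate 1 (up to 0.171, without sKO LZ replicate 1). The neutrophil gene S100a8 was at 3.03 and 21.7 FPKM in the sKO LZ and 5.51 and 53.1 in the dKO LZ libraries, so that Tyrobp and S100a8 were both highest in dKO LZ replicate 2. Of 9 myeloid marker genes tested, 1 rose (Hmox1, which is also on the heme list) and 1 fell (Mpeg1), as did adjusted over the list alone (camera adjusted p = 0.287; 0.025 without dKO LZ replicate 1). Without dKO LZ replicate 1, 3 of them rose, and the list median was 0.133 to 1.344 when 1 library was left out (0.91 with all).

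Genes of growth and biosynthesis were higher in dKO LZ cells. Of 40 MYC target and ribosome biogenesis genes, 37 rose and 0 fell (38 rose adjusted over the list alone), with a list median of 0.54. The nucleolar genes Nolc1 and Gnl3 went from 34.5 ± 0.0687 to 57.6 ± 0.786 FPKM and from 41.3 ± 1.35 to 64.3 ± 0.109 (adjusted p = 0.000884 and 0.000884, limma). Of 29 G1/S and DNA replication genes, 26 rose (27 adjusted over the list alone), among them the clamp loader gene Rfc4 (0.56 ± 0.040) and Uhrf1, which maintains DNA methylation (0.58 ± 0.047). Of 30 genes of amino acid supply driven by mTORC1 and ATF4, 18 rose and 2 fell (21 and 2 adjusted over the list alone). The asparagine synthetase gene Asns went from 8.42 ± 0.761 to 16.7 ± 0.231 (0.92 ± 0.070). Slc7a5, a large neutral amino acid transporter gene, went from 21.4 ± 0.562 to 35.8 ± 0.223 (0.71 ± 0.059, adjusted p = 0.00102). Of 22 cholesterol synthesis genes 15 rose (17 adjusted over the list alone). Of 20 glycolysis genes 11 rose (12 rose and 1 fell adjusted over the list alone), led by Aldoa, from 205 ± 6.88 to 371 ± 5.63. Of 42 respiratory chain genes 19 rose (20 adjusted over the list alone) with a median of 0.20. That count was 9 without sKO LZ replicate 2, 8 without dKO LZ replicate 1 and 9 without dKO LZ replicate 2.

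The heme and oxidative stress list, which holds known BACH and NRF2 targets, had 7 of 12 genes higher in dKO LZ cells and 0 lower (7 higher adjusted over the list alone). The inducible heme oxygenase gene Hmox1 went from 0.611 ± 0.115 to 3.08 ± 0.000113 FPKM (1.34 ± 0.083, adjusted p = 0.000884), the thioredoxin reductase gene Txnrd1 from 19.7 ± 1.68 to 31.9 ± 1.03 and the peroxiredoxin gene Prdx1 from 272 ± 2.13 to 374 ± 7.82. Camera compares the changes of a list with those of all other genes. The MYC list gave adjusted p = 3.25e-17 by camera and adjusted p = 0.104 with an estimated correlation. The G1/S list gave adjusted p = 9.62e-12 by camera and adjusted p = 0.145 with an estimated correlation. The cholesterol list gave adjusted p = 3.1e-07 by camera and adjusted p = 0.104 with an estimated correlation. The mTORC1 and ATF4 list gave adjusted p = 7.73e-06 by camera and adjusted p = 0.11 with an estimated correlation. The respiratory chain list gave adjusted p = 1.34e-05 by camera and adjusted p = 0.467 with an estimated correlation. The glycolysis list gave adjusted p = 0.000285 by camera and adjusted p = 0.276 with an estimated correlation. The heme list gave adjusted p = 0.00427 by camera and adjusted p = 0.276 with an estimated correlation. Each of these camera calls held without each single library, and each was lost with the estimated correlation. The 28 cytosolic ribosomal protein genes had a median of -0.041 (-0.056 to -0.017 with 1 library left out) and no member past the threshold, over all genes or adjusted over the list alone (camera adjusted p = 0.0684).

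Receptors and memory genes were lower in dKO LZ cells. Of 23 survival receptor genes (BAFF, cytokine and antigen receptor components), 0 rose and 17 fell (17 adjusted over the list alone; 10 without dKO LZ replicate 1). The kinase gene Syk went from 152 ± 2.56 to 109.5 ± 0.767 FPKM (-0.47 ± 0.037). The complement receptor gene Cr2 went from 92.4 ± 13.0 to 53.3 ± 1.32 and Cd22 from 288 ± 3.33 to 218 ± 7.32 (adjusted p 0.000979 to 0.00208, limma). Of 25 memory B cell and memory precursor genes, 1 rose and 12 fell (2 and 14 adjusted over the list alone). Ccr6, a chemokine receptor of memory precursors, went from 3.25 ± 0.209 to 0.772 ± 0.107 (-1.26 ± 0.11, adjusted p = 0.0011). The memory transcription factor gene Hhex went from 4.57 ± 0.420 to 1.62 ± 0.227 (-1.09 ± 0.12) and Cd38, whose protein was gated against in the sort, from 13.8 ± 1.45 to 6.78 ± 0.461 (-0.92 ± 0.084). Of 12 markers of naive and marginal zone B cells 1 rose and 5 fell (1 and 6 adjusted over the list alone). Fcer2a (CD23) went from 281 ± 15.5 to 142 ± 2.92, and the Fc receptor-like gene Fcrl1 changed by -0.65 ± 0.037. Klf2, on the memory and naive lists, was at 10.6 and 3.94 in the sKO LZ libraries and 3.00 and 4.14 in the dKO LZ libraries.

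Of 29 light zone genes, 1 rose and 6 fell in dKO LZ cells (1 and 5 adjusted over the list alone), among the lower ones Fcer2a, the secreted amino acid oxidase gene Il4i1 (-0.74 ± 0.091) and Cd72 (-0.45 ± 0.065). Of 27 NF-kB and CD40 response genes 1 rose and 6 fell (1 and 4 adjusted over the list alone; 3 fell without sKO LZ replicate 2). The chemokine gene Ccl22 went from 2.77 ± 0.00653 to 0.387 ± 0.167 FPKM (-1.45 ± 0.12, adjusted p = 0.00107) and the NF-kB inhibitor gene Nfkbie changed by -0.27 ± 0.040. Of 13 genes of cell cycle inhibition and quiescence 1 rose and 4 fell, the same counts as adjusted over the list alone. The anti-proliferative genes Btg1 and Btg2 changed by -0.85 ± 0.080 and -0.48 ± 0.041 and the p27 gene Cdkn1b by -0.93 ± 0.10 (adjusted p 0.00107 to 0.00191, limma). The survival receptor list gave adjusted p = 1.27e-07 by camera and adjusted p = 0.104 with an estimated correlation. The memory list gave adjusted p = 9.78e-06 by camera and adjusted p = 0.11 with an estimated correlation. The naive and marginal zone list gave adjusted p = 0.00558 by camera and adjusted p = 0.145 with an estimated correlation. The light zone list gave adjusted p = 0.00632 by camera and adjusted p = 0.153 with an estimated correlation. The NF-kB list gave adjusted p = 0.00683 by camera and adjusted p = 0.153 with an estimated correlation. The quiescence list gave adjusted p = 0.0203 by camera and adjusted p = 0.189 with an estimated correlation. Each of these camera calls held without each single library and was lost with the estimated correlation.

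Germinal centre and plasma cell genes were mixed in dKO LZ cells. Of 26 germinal centre identity genes 2 rose and 4 fell, the same counts as adjusted over the list alone (camera adjusted p = 0.379; 1 rose without sKO LZ replicate 2, dKO LZ replicate 1 or dKO LZ replicate 2). The sphingosine phosphate receptor gene S1pr2 went from 114 ± 5.77 to 141 ± 1.98 FPKM (0.31 ± 0.048, adjusted p = 0.00522). The transcription factor gene Spib changed by -0.31 ± 0.040. Bcl6, the germinal centre master regulator, was at 125 ± 7.18 and 116 ± 3.14 (-0.097 ± 0.049, adjusted p = 0.181; 0.0442 with upper quartile scaling and 0.0341 with quantile normalization). The plasma cell factor gene Irf4 was at 11.3 ± 0.447 and 12.9 ± 0.115 (0.296) and Myc at 37.1 ± 6.42 and 53.9 ± 2.01 (0.54 ± 0.27, 0.174). Myc in LZ passed without sKO DZ replicate 1 (0.0218), without sKO DZ replicate 2 (0.0217) and without both sKO replicate 1 libraries (0.00701). Of 25 plasma cell genes 10 rose and 2 fell (10 and 3 adjusted over the list alone; 5 rose without dKO LZ replicate 1 and 6 without dKO LZ replicate 2). Manf, an endoplasmic reticulum stress gene, and the J chain gene Igj rose by 0.39 ± 0.052 and 0.24 ± 0.038. The chemokine receptor gene Cxcr3 fell from 2.67 ± 0.336 to 0.127 ± 0.0926 (-1.70 ± 0.15). Camera gave adjusted p = 0.0231 for the plasma cell list, 0.0593 without sKO LZ replicate 1 and adjusted p = 0.153 with an estimated correlation. Among death regulators, Bcl2l11, which encodes the pro-apoptotic protein BIM, rose from 7.60 ± 0.637 to 16.0 ± 0.113 (0.99 ± 0.064, adjusted p = 0.000884). Bmf, another pro-apoptotic gene, fell from 12.3 ± 0.823 to 6.13 ± 0.0448 and the pro-survival gene Mcl1 from 192 ± 2.18 to 150.5 ± 1.40. The sorting markers Cd86 and Cxcr4 were at 98.3 ± 10.5 and 78.1 ± 0.963 and at 75.9 ± 3.35 and 76.0 ± 2.29. Adjusted p was 0.0238 for Cd86 (0.0721 without sKO LZ replicate 2, 0.105 and 0.0841 without dKO LZ replicates 1 and 2) and 0.98 for Cxcr4.

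In LZ, 3299 of 10610 genes tested (31.1%) passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 1948 higher and 1351 lower in dKO. Of these, 39 of the higher and 32 of the lower ones changed by at least 1 on the log2 scale, and the median size of change among the genes called was 0.35. The share of higher genes, 59%, was 45.5% with upper quartile scaling, so the balance between higher and lower genes depended on the scaling. The count was 1703 without dKO LZ replicate 1, 1948 without dKO LZ replicate 2 and 2177 when only the LZ libraries were fitted.

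**Figure D1:**
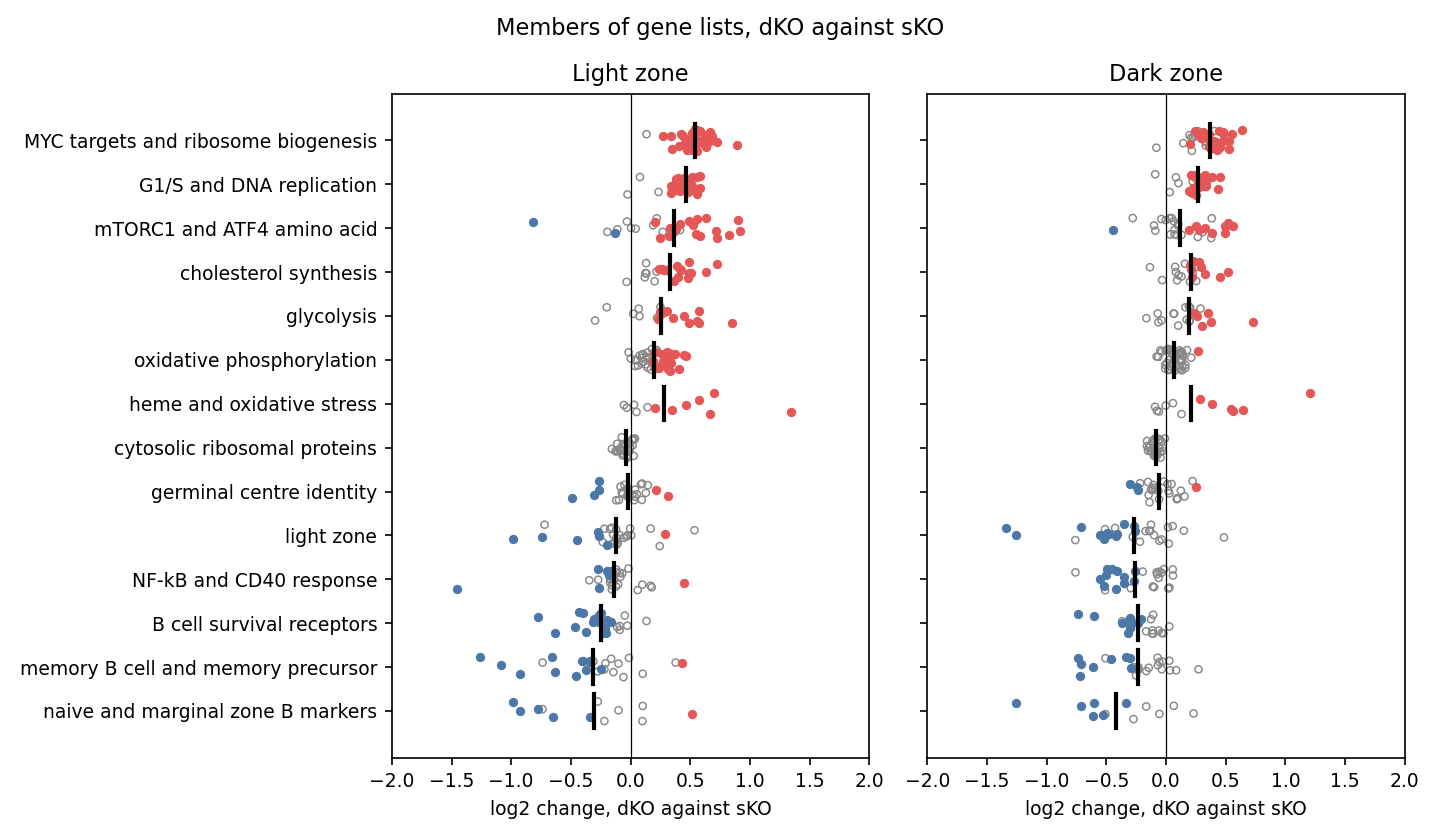
Change between dKO and sKO (log2(FPKM + 1) scale, x axis) of each tested member of 14 gene lists in LZ (left) and DZ (right) cells. Filled red points are members past an adjusted p of 0.05 and higher in dKO, filled blue points those lower in dKO, open points the rest, and black bars list medians; the MYC list has its median at 0.54 in LZ and 0.37 in DZ, and the survival receptor list at -0.24 in both zones.

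The same comparison in DZ cells gave a largest rise in Mgll as well, from 1.29 ± 0.0546 FPKM in sKO to 8.41 ± 0.883 in dKO (2.03 ± 0.095). Next came St3gal6, from 9.54 ± 0.508 to 36.8 ± 0.0110 (1.84 ± 0.048), the stress-induced cytokine gene Gdf15 (1.62 ± 0.22), Palm (1.60 ± 0.099) and the membrane repair gene Myof (1.51 ± 0.098). The cyclic nucleotide phosphodiesterase gene Pde2a went from 19.2 ± 0.649 to 51.0 ± 0.0321 (1.36 ± 0.045). Alcam, the ubiquitin hydrolase gene Uchl1, Mettl7a1 and Hmox1 rose by 1.20 to 1.34 (adjusted p 2.48e-05 to 0.00996 over these 10 genes, limma). Il4i1 fell from 10.1 ± 0.764 to 3.38 ± 0.406 (-1.34 ± 0.091), Fcer2a from 69.9 ± 1.52 to 28.6 ± 0.881 (-1.26 ± 0.050) and Grm6 and Gbp2 by 1.18 and 1.09. The glycolipid synthesis gene B3gnt5, the lymphocyte quiescence gene Slfn2, the MAP kinase phosphatase gene Dusp4, the GTPase gene Gimap3, the glutathione transferase gene Gstt1 and Litaf changed by -0.99 to -0.87 (adjusted p 0.000157 to 0.0141 over the 10 lower genes, limma). Of these 20 genes 16 passed without each single library in turn. Gdf15, Mettl7a1, Slfn2 and Gstt1 lost the call without dKO DZ replicate 1 (adjusted p = 0.0749, 0.0617, 0.0574 and 0.0928) and without dKO DZ replicate 2 (0.0701, 0.0557, 0.051 and 0.0783). Gdf15 and Gstt1 lost it also without sKO DZ replicate 1 (0.0551 and 0.0701) and Gstt1 without sKO DZ replicate 2 (0.061).

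Growth and biosynthesis genes were also higher in dKO DZ cells. Of 40 MYC target and ribosome biogenesis genes 26 rose and 0 fell (37 rose adjusted over the list alone), with a list median of 0.37 (0.33 to 0.40 without each single library). Mybbp1a, a nucleolar transcription cofactor gene, went from 46.9 ± 0.280 to 63.1 ± 0.260 FPKM and Nolc1 from 23.7 ± 0.949 to 35.3 ± 1.35 (adjusted p 0.00223 to 0.00294, limma). Of 29 G1/S genes 20 rose (24 adjusted over the list alone; median 0.26). Of 22 cholesterol synthesis genes 9 rose (14 adjusted over the list alone, median 0.21). Of 30 mTORC1 and ATF4 genes 10 rose and 1 fell (13 and 1 adjusted over the list alone, median 0.12). Of 20 glycolysis genes 6 rose (7 adjusted over the list alone, median 0.19). Cad, which starts pyrimidine synthesis, rose by 0.53 ± 0.052, Slc7a5 by 0.56 ± 0.059 (adjusted p = 0.00537, limma; 0.0559 without dKO DZ replicate 1) and Aldoa by 0.73 ± 0.059. Of 12 heme and oxidative stress genes 6 rose (6 adjusted over the list alone), with Hmox1 from 1.85 ± 0.0824 to 5.55 ± 0.216. Without sKO DZ replicate 1, sKO DZ replicate 2, dKO DZ replicate 1 and dKO DZ replicate 2 in turn, the number of genes that rose was 17, 26, 7 and 4 in the MYC list, 3, 8, 0 and 0 in G1/S, 2, 3, 0 and 0 in cholesterol. In the same order it was 5, 10, 1 and 3 in mTORC1 and ATF4, 1, 6, 1 and 1 in glycolysis and 4, 3, 1 and 1 in heme. Without dKO LZ replicate 1 or 2 it was 12 in G1/S, 5 in cholesterol and 2 in glycolysis.

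By camera these lists were higher in DZ as well. The MYC list gave adjusted p = 3.64e-18 by camera and adjusted p = 0.0686 with an estimated correlation. The G1/S list gave adjusted p = 1.32e-10 by camera and adjusted p = 0.121 with an estimated correlation. The cholesterol list gave adjusted p = 2.41e-06 by camera and adjusted p = 0.0699 with an estimated correlation. The mTORC1 and ATF4 list gave adjusted p = 0.000436 by camera and adjusted p = 0.12 with an estimated correlation. The glycolysis list gave adjusted p = 0.00111 by camera and adjusted p = 0.363 with an estimated correlation. The heme list gave adjusted p = 0.00393 by camera and adjusted p = 0.34 with an estimated correlation. The 6 camera calls held without each single library and were lost with the estimated correlation. Of 42 respiratory chain genes 1 rose, Cycs, which encodes cytochrome c (0.27 ± 0.054), and 0 adjusted over the list alone; camera gave adjusted p = 0.034 for the list, 0.934 without sKO DZ replicate 1, 0.0634 without dKO DZ replicate 2 and adjusted p = 0.681 with an estimated correlation. The Cycs call was lost without dKO LZ replicate 1 (0.062), dKO LZ replicate 2 (0.0621), sKO DZ replicate 1 (0.124), sKO DZ replicate 2 (0.0635), dKO DZ replicate 1 (0.109), dKO DZ replicate 2 (0.162). The 28 cytosolic ribosomal protein genes had a median of -0.081 (-0.16 to -0.029 with 1 library left out) with no member past the threshold, over all genes or adjusted over the list alone (camera adjusted p = 0.000297, 0.118 without sKO DZ replicate 2, and adjusted p = 0.574 with an estimated correlation).

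Receptor, light zone and NF-kB genes were lower in dKO DZ cells. Of 23 survival receptor genes 0 rose and 12 fell (17 adjusted over the list alone; median -0.24), among them Syk, from 196 ± 5.44 to 159 ± 2.87 FPKM, and the inhibitory Fc receptor gene Fcgr2b, from 97.4 ± 0.529 to 77.5 ± 1.04. Of 29 light zone genes 12 fell (13 adjusted over the list alone; median -0.27). Of 27 NF-kB and CD40 response genes 11 fell (13 adjusted over the list alone; median -0.26). Nfkb2, the precursor of p52, went from 27.2 ± 0.348 to 19.7 ± 1.12 (-0.45 ± 0.047, adjusted p = 0.00555). Of 25 memory genes 8 fell (1 rose and 9 fell adjusted over the list alone; median -0.23, -0.24 to -0.14 with 1 library left out), including Cd38 (-0.61 ± 0.084) and Cd22, from 183 ± 6.36 to 148 ± 4.72. Of 12 naive and marginal zone markers 6 fell (6 adjusted over the list alone), including Fcer2a and Fcrl1 (-0.53 ± 0.037). The calls for Syk, Fcgr2b, Cd38 and Cd22 were lost without dKO DZ replicate 1 (0.0651, 0.0599, 0.074 and 0.0976) or replicate 2 (0.072, 0.0633, 0.0723 and 0.0709). Those for Cd38 and Cd22 were lost also without sKO DZ replicate 1 (0.0579 and 0.0613). Without sKO DZ replicate 1, sKO DZ replicate 2, dKO DZ replicate 1 and dKO DZ replicate 2 in turn, the number of genes that fell was 7, 7, 0 and 0 in survival receptors, 5, 8, 4 and 3 in light zone. In the same order it was 4, 7, 1 and 1 in NF-kB, 1, 4, 0 and 0 in memory and 3, 5, 2 and 2 in naive and marginal zone, and 7 in NF-kB without dKO LZ replicate 1 or 2. The survival receptor list gave adjusted p = 1.9e-09 by camera and adjusted p = 0.0686 with an estimated correlation. The light zone list gave adjusted p = 1.84e-07 by camera and adjusted p = 0.0686 with an estimated correlation. The NF-kB list gave adjusted p = 1.93e-06 by camera and adjusted p = 0.0686 with an estimated correlation. The memory list gave adjusted p = 4.84e-05 by camera and adjusted p = 0.101 with an estimated correlation. The naive and marginal zone list gave adjusted p = 0.000143 by camera and adjusted p = 0.0699 with an estimated correlation. These 5 camera calls held without each single library and were lost with the estimated correlation. Klf2, on the memory and naive lists, was at 11.3 and 3.49 FPKM in the sKO DZ libraries and 4.38 and 4.07 in the dKO DZ libraries.

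Bcl2l11 rose in DZ cells too, from 13.4 ± 0.600 to 26.0 ± 0.232 FPKM (0.91 ± 0.064, adjusted p = 0.00155, limma), and S1pr2 from 136 ± 5.45 to 163 ± 1.39 (adjusted p = 0.0235). Irf4 fell from 3.53 ± 0.733 to 2.17 ± 0.255 (adjusted p = 0.0417). The Irf4 call was lost without any library except sKO DZ replicate 2 (up to 0.204, without dKO DZ replicate 1). That of S1pr2 was lost without dKO LZ replicate 1 (0.0534), dKO LZ replicate 2 (0.0536), sKO DZ replicate 1 (0.0987), dKO DZ replicate 1 (0.122), dKO DZ replicate 2 (0.138). Bcl6 was at 124 ± 2.95 and 119 ± 1.17 (adjusted p = 0.502) and Myc at 20.9 ± 9.16 and 28.3 ± 0.199 (0.298). Myc in DZ passed without sKO DZ replicate 1 (0.0383) and without both sKO replicate 1 libraries (0.0118). Ccr6 was near 0 in DZ cells, at 0.0592 ± 0.0837 and 0.0319 ± 0.0452 (0.878). The sorting markers Cd86 and Cxcr4 were at 36.6 ± 2.56 and 31.7 ± 0.645 (0.162, and 0.0463 without both sKO replicate 1 libraries) and 134 ± 4.07 and 134 ± 6.79 (0.974). Of 26 germinal centre identity genes 1 rose and 3 fell, as adjusted over the list alone. Of 25 plasma cell genes 4 rose and 5 fell (6 and 6 adjusted over the list alone). Camera gave adjusted p = 0.132 and 0.553. Without sKO DZ replicates 1 and 2 the plasma cell counts were 1 and 2 higher and 3 and 2 lower, without either dKO LZ library 1 higher and 3 lower, and without either dKO DZ library 0 and 0. The germinal centre list had 1 lower without either dKO LZ library and 0 without either dKO DZ library.

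In DZ, 1258 of 10610 genes (11.9%) passed the threshold (limma, Benjamini-Hochberg), 703 higher and 555 lower in dKO, of which 23 and 11 changed by at least 1 on the log2 scale. Leaving out a library also lowers the degrees of freedom, so a lower count does not show reliance on that library. The DZ count fell further than the LZ count when 1 library of the contrast was left out. It was 105 without dKO DZ replicate 1, 107 without dKO DZ replicate 2, 378 without sKO DZ replicate 1, and 551 without sKO DZ replicate 2. It was 756 without dKO LZ replicate 1 or replicate 2, 501 without both sKO replicate 1 libraries and 649 when only the DZ libraries were fitted.

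**Figure D2:**
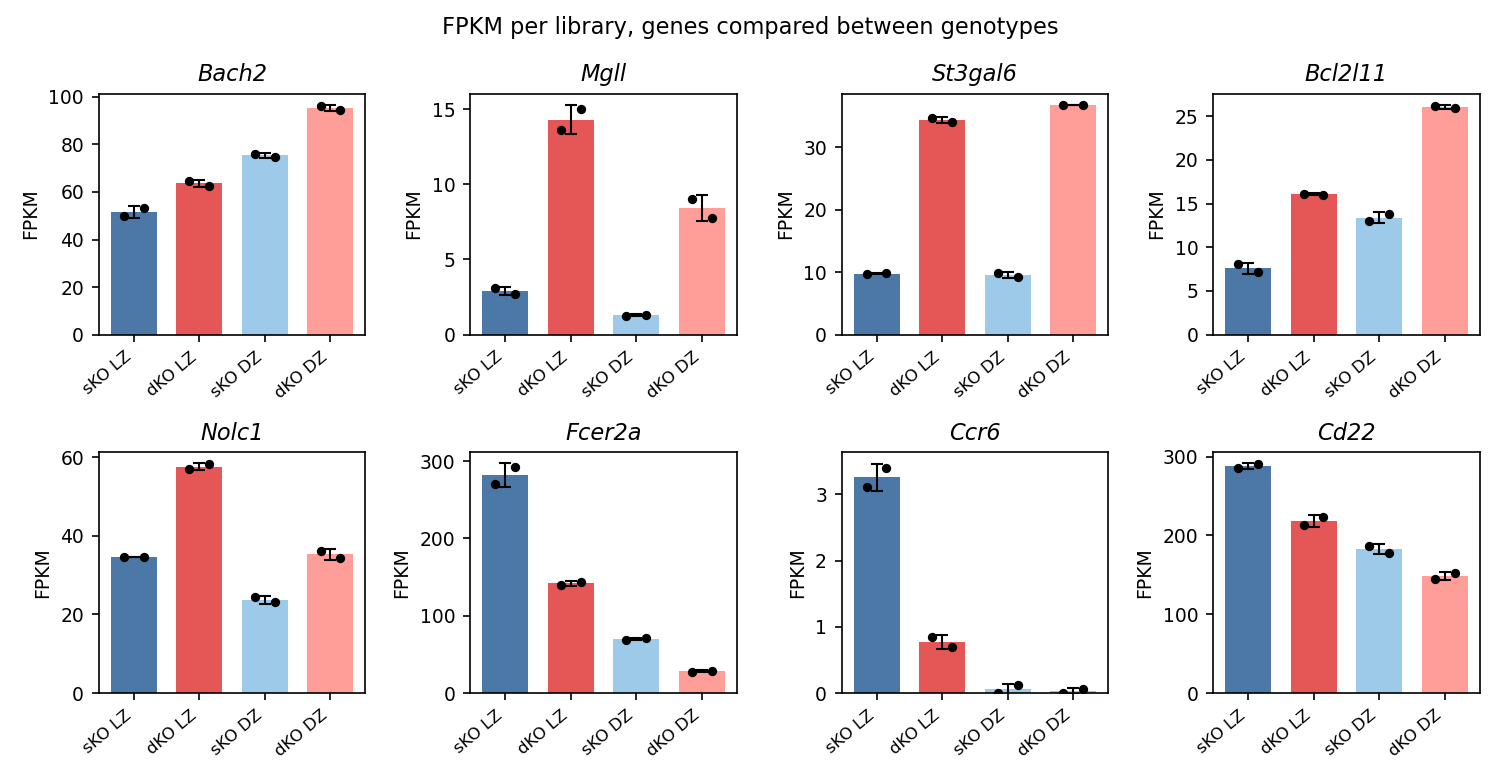
FPKM of 8 genes in the 4 groups, with bars for the mean, error bars for the SD (n = 2) and points for the 2 libraries. Mgll, St3gal6, Bcl2l11 and Nolc1 were higher in dKO in both zones, Fcer2a and Cd22 lower, and Ccr6 reached 3.25 FPKM in sKO LZ and 0.772 in dKO LZ.

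The genotype effects in the zones, which share no library, were then set side by side. The labels do not say whether same-numbered LZ and DZ libraries came from the same pool of mice. Of the genes called higher, 616 were shared between LZ and DZ where 129.1 were expected of independent lists. Of those called lower 481 were shared where 70.7 were expected. Only 8 genes were called in opposite directions (191.4 expected). Both contrasts took each gene's variance from the same fit of all 8 libraries. The lists are therefore not independent, and the expected numbers are only a loose guide. Across 7775 genes with a mean of at least 5 FPKM the changes correlated at 0.767 (Pearson), genes not being independent replicates. Of the 3299 genes called in LZ, 3128 (94.8%) had the same sign in DZ, and the median ratio of the DZ to the LZ change was 0.563. Choosing genes by their LZ change biases this ratio downward, so it does not give the relative size of the DZ effect. In the mean of both zones, Mgll (2.00 ± 0.067), St3gal6 (1.78 ± 0.034), Palm and Myof (1.44 ± 0.070) rose most among ranked genes with no read-sharing copies, and Rpl26, with its pseudogenes, rose by 1.34 ± 0.33. Capg (-1.30 ± 0.12), Gbp2, Grm6, Fcer2a and Il4i1 were the ranked genes that fell most. Their adjusted p values were 3.32e-06 to 0.000784, and 0.0211 for Rpl26, which lost the call without sKO LZ replicate 1 (0.0539), sKO DZ replicate 2 (0.0654), dKO DZ replicate 1 (0.0599), dKO DZ replicate 2 (0.0618). In all, 3942 genes passed (2301 higher, 1641 lower; limma, Benjamini-Hochberg), a share of 58.4% higher that was 46.9% with upper quartile scaling. The MYC list had 38 of 40 genes higher (39 adjusted over the list alone) and the survival receptor list 18 of 23 lower (19 adjusted over the list alone). They had camera adjusted p = 6.26e-17 and 7.34e-09, and adjusted p = 0.0767 with an estimated correlation for both.

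**Figure D3:**
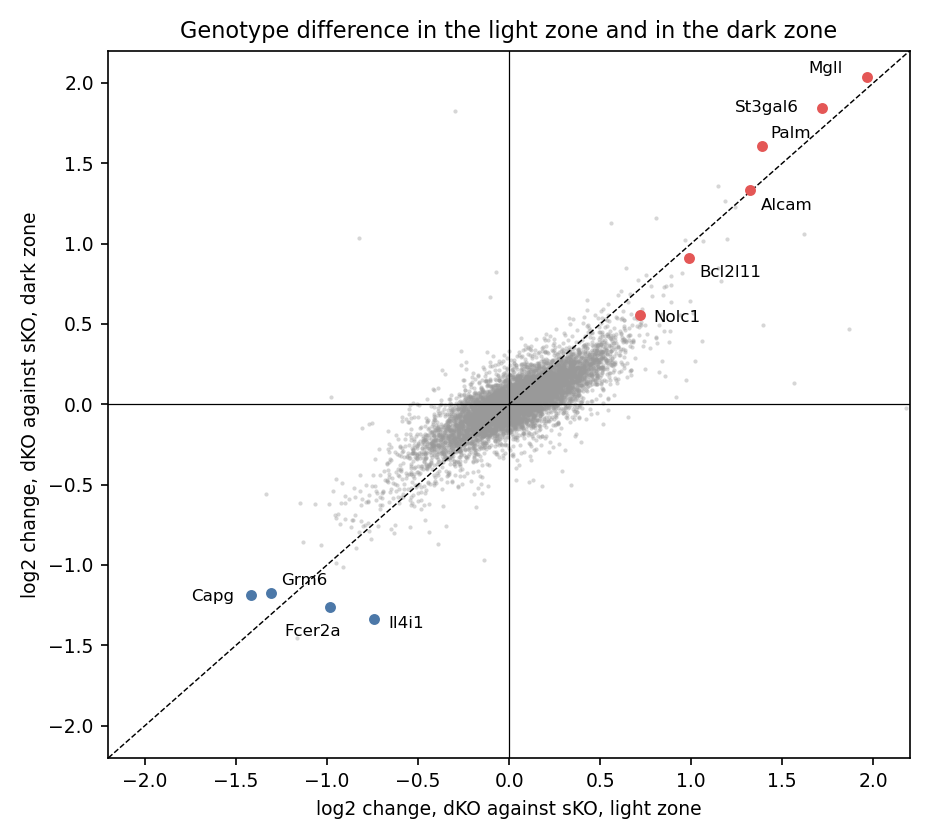
Change between dKO and sKO on the log2(FPKM + 1) scale in LZ (x axis) and in DZ (y axis) for 7775 genes with a mean of at least 5 FPKM, each point a gene; 4 points beyond the axes are not drawn. Named genes higher in dKO are red and those lower are blue, the dashed line marks equal change, and the changes correlated at 0.767 across genes.

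Whether the genotype effect differed between zones was tested as an interaction. Only 3 of 10610 genes passed (limma, Benjamini-Hochberg). All 3 were microRNA genes listed at 0 in at least 4 of the 8 libraries, and with small RNA genes left out the count was 0. At an unadjusted p under 0.05 (limma) there were 1232 genes, a larger share than the 0.05 due if no gene differed. The simulation held 0 genes with a changed interaction, so the power of this test was not measured. The few calls thus do not show that the genotype effects were equal in the zones. The protein-coding genes with the smallest p were taken among those with a mean of at least 5 FPKM on either side of the contrast, and none passed. They were Batf, an AP-1 factor of germinal centre B cells (0.70 ± 0.077), Asns (0.87 ± 0.099), the mitochondrial ribosome gene Mrpl13 (0.44 ± 0.051) and the fatty acid receptor gene Cd36 (-0.57 ± 0.067), each with adjusted p = 0.142, and Clic4 (0.42 ± 0.057, 0.207). Batf was at 35.8 ± 0.669 FPKM in sKO LZ, 43.9 ± 1.92 in dKO LZ, 11.2 ± 0.0556 in sKO DZ and 8.12 ± 0.464 in dKO DZ. Asns was at 8.42 ± 0.761, 16.7 ± 0.231, 5.56 ± 0.000672 and 5.78 ± 0.244. Genes called in a single zone did not pass either, such as Ccr6 (-1.23 ± 0.16, adjusted p = 0.177), Hhex (0.285) and Irf4 (0.336). By camera the genotype change was higher in LZ than in DZ for 7 lists and lower for the memory list. The MYC list gave adjusted p = 7.03e-09 by camera and adjusted p = 0.285 with an estimated correlation. The G1/S list gave adjusted p = 7.48e-08 by camera and adjusted p = 0.285 with an estimated correlation. The respiratory chain list gave adjusted p = 5.71e-05 by camera and adjusted p = 0.528 with an estimated correlation. The mTORC1 and ATF4 list gave adjusted p = 0.000142 by camera and adjusted p = 0.285 with an estimated correlation. The cholesterol list gave adjusted p = 0.000347 by camera and adjusted p = 0.285 with an estimated correlation. The light zone list gave adjusted p = 0.00803 by camera (0.313 without sKO DZ replicate 1) and adjusted p = 0.285 with an estimated correlation. The glycolysis list gave adjusted p = 0.0188 by camera (0.0983 without sKO LZ replicate 2, 0.0729 without dKO LZ replicate 1, 0.0735 without dKO DZ replicate 1) and adjusted p = 0.528 with an estimated correlation. The memory list gave adjusted p = 0.0379 by camera (0.207 without sKO LZ replicate 2, 0.169 without dKO LZ replicate 1, 0.0744 without sKO DZ replicate 2, 0.0528 without dKO DZ replicate 1) and adjusted p = 0.349 with an estimated correlation. The light zone list, lower in dKO, was less lowered in LZ. Each camera call was lost with the estimated correlation. No member of these lists passed over all genes, and adjusted over the list alone 2 MYC, 5 G1/S, 1 respiratory chain, 1 mTORC1 and ATF4, 1 cholesterol, 2 light zone and 1 glycolysis genes were higher and 3 memory genes lower.

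The zones were compared within sKO cells. Il4i1 was the most raised of the ranked genes in LZ over DZ cells, at 98.7 ± 6.67 against 10.1 ± 0.764 FPKM (3.17 ± 0.091). Next came the G1 cyclin gene Ccnd2, at 6.52 ± 0.819 against 0.188 ± 0.0452 (2.66 ± 0.10). Others were the properdin gene Cfp (1.99 ± 0.16), Fcer2a (1.99 ± 0.050) and Snn (1.87 ± 0.096). The pro-survival genes Bcl2a1b, Bcl2a1d and Bcl2a1a were higher by 1.95 to 2.08, but are near-identical copies that can share reads. Higher in DZ were the linker histone gene H1fx (-1.81 ± 0.20) and Pafah1b3, at 49.8 ± 4.94 against 175 ± 4.18 (-1.80 ± 0.089). So were Serinc5 (-1.79 ± 0.079), the selenoprotein P gene Sepp1 (-1.73 ± 0.054) and the germinal centre gene Gcet2, at 36.1 ± 4.19 against 117 ± 5.16 (-1.68 ± 0.076). The deubiquitinase gene Otub2, Pde2a and Arl5c changed by -1.65 to -1.53. Adjusted p ranged from 1.92e-05 to 0.00135 over the 16 genes (limma), all of which passed without each single library. The sorting markers followed the gate, which makes them no finding. Cd86 was at 98.3 ± 10.5 in LZ and 36.6 ± 2.56 in DZ, and Cxcr4 at 75.9 ± 3.35 and 134 ± 4.07.

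Of 29 light zone genes 22 rose in LZ over DZ cells and 1 fell (24 and 1 adjusted over the list alone; median 0.92). Among them were the activation marker gene Cd83, at 339 ± 27.6 against 96.5 ± 2.65 FPKM, and Batf (1.60 ± 0.054). Of 27 NF-kB and CD40 response genes 22 rose and 0 fell (23 rose adjusted over the list alone), with Slamf1 (1.40 ± 0.052), the inhibitor of apoptosis gene Birc3 (1.03 ± 0.039) and Cd40 itself (1.33 ± 0.056). The light zone list gave adjusted p = 6.63e-15 by camera and adjusted p = 0.0263 with an estimated correlation. The NF-kB list gave adjusted p = 2.14e-14 by camera and adjusted p = 0.0263 with an estimated correlation. These were the only list calls that held with the estimated correlation in this comparison. The light zone and dark zone lists name genes of the cells that the gate selects, so their direction checks the sort. Of 27 dark zone genes 25 fell and 1, Rgs13, rose (25 and 1 adjusted over the list alone), with the translesion polymerase gene Polh (-1.25 ± 0.075) and the mitotic gene Hmmr (-0.73 ± 0.042) as examples (camera adjusted p = 2.08e-13, and adjusted p = 0.182 with an estimated correlation). Of 40 MYC target genes 32 rose (34 adjusted over the list alone), with Gnl3 at 41.3 ± 1.35 against 20.6 ± 0.348. Of 29 G1/S genes 0 rose and 24 fell (1 and 26 adjusted over the list alone). The MYC list gave adjusted p = 9.36e-14 by camera and adjusted p = 0.156 with an estimated correlation. The G1/S list gave adjusted p = 4.48e-09 by camera and adjusted p = 0.182 with an estimated correlation. Bach2 was lower in LZ (-0.54 ± 0.044, adjusted p = 0.000499), as was Bcl2l11 (-0.74 ± 0.064), while Irf4 (1.45 ± 0.12), Ccr6 (2.01 ± 0.11) and Slc7a5 (0.49 ± 0.059) were higher (adjusted p 0.000165 to 0.00185 over the last 4 genes, limma).

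Of 22 cholesterol synthesis genes 15 rose in LZ over DZ sKO cells and 1 fell (15 and 2 adjusted over the list alone; 9 rose without sKO DZ replicate 1), led by Sc4mol (0.59 ± 0.057). Of 30 mTORC1 and ATF4 genes 12 rose and 2 fell (14 and 3 adjusted over the list alone). Of 25 plasma cell genes 10 rose and 2 fell (12 and 3 adjusted over the list alone), the protein degradation gene Derl3 rising by 1.34 ± 0.048 and Igj changing by -0.63 ± 0.038. Of 23 survival receptor genes 12 rose and 4 fell (13 and 4 adjusted over the list alone), Cd40 and the cytokine receptor gene Il2rg (0.91 ± 0.046) rising. Only 1 fell without sKO LZ replicate 2 or sKO DZ replicate 2 and 2 without sKO DZ replicate 1. The cholesterol list gave adjusted p = 9.59e-05 by camera and adjusted p = 0.166 with an estimated correlation. The mTORC1 and ATF4 list gave adjusted p = 0.00105 by camera and adjusted p = 0.172 with an estimated correlation. The plasma cell list gave adjusted p = 0.008 by camera and adjusted p = 0.166 with an estimated correlation. The survival receptor list gave adjusted p = 0.00105 by camera and adjusted p = 0.172 with an estimated correlation. Of 21 antigen receptor response genes 8 rose and 3 fell (12 and 3 adjusted over the list alone, 6 to 11 and 2 to 3 with 1 library left out). Of 9 pro-survival genes 6 rose and 1 fell (6 and 1 adjusted over the list alone, 5 to 7 and 1 with 1 library left out). Of 12 heme and oxidative stress genes 0 rose and 7 fell (0 and 7 adjusted over the list alone, 0 and 5 to 6 with 1 library left out). Of 25 memory genes 11 rose and 6 fell (13 and 6 adjusted over the list alone, 6 to 10 and 4 to 5 with 1 library left out). Of 42 respiratory chain genes 2 rose and 10 fell (2 and 10 adjusted over the list alone, 0 to 2 and 4 to 13 with 1 library left out). The antigen receptor list gave adjusted p = 0.00134 by camera and adjusted p = 0.197 with an estimated correlation. The pro-survival list gave adjusted p = 0.00105 by camera and adjusted p = 0.207 with an estimated correlation. The heme list gave adjusted p = 0.00564 by camera and adjusted p = 0.263 with an estimated correlation. The memory list gave adjusted p = 0.0301 by camera (0.0625 without sKO DZ replicate 2) and adjusted p = 0.25 with an estimated correlation. The respiratory chain list gave adjusted p = 0.0367 by camera (0.078 without sKO LZ replicate 2 and 0.491 without sKO DZ replicate 2) and adjusted p = 0.69 with an estimated correlation. In sKO, 3312 genes differed between zones (1609 higher and 1703 lower in LZ; limma, Benjamini-Hochberg), and 2077 without sKO LZ replicate 2, 2001 without sKO DZ replicate 2 and 1678 when only the sKO libraries were fitted.

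In dKO cells the zones differed in similar genes. Il4i1 was at 58.6 ± 3.49 in LZ against 3.38 ± 0.406 FPKM in DZ (3.77 ± 0.091), Tnfrsf8 (CD30) at 9.13 ± 0.368 against 0.562 ± 0.0580 (2.70 ± 0.088) and Ccnd2 at 6.48 ± 0.0110 against 0.202 ± 0.0705 (2.64 ± 0.10). Sepp1 (-2.08 ± 0.054), Pafah1b3 (-1.85 ± 0.089), Tifa, an adaptor of NF-kB signalling (-1.82 ± 0.16), Pde2a (-1.80 ± 0.045) and Arl5c (-1.77 ± 0.089) were higher in DZ, with adjusted p 1.37e-05 to 0.00051 over these 8 genes (limma). The myeloid genes S100a8 (3.86 ± 1.12, adjusted p = 0.0397) and Lyz2 (3.21 ± 0.79, adjusted p = 0.0227) were also called. Their levels in dKO LZ replicates 1 and 2 were 5.51 and 53.1 FPKM for S100a8 and 4.91 and 24.8 for Lyz2. The S100a8 call was lost without dKO LZ replicate 2 (0.153), sKO DZ replicate 1 (0.0639), sKO DZ replicate 2 (0.0641), dKO DZ replicate 1 (0.106), dKO DZ replicate 2 (0.156) and the Lyz2 call without dKO LZ replicate 2 (0.0876), dKO DZ replicate 1 (0.0897), dKO DZ replicate 2 (0.092).

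Of 29 light zone genes 23 rose in LZ over DZ dKO cells and 1 fell (25 and 1 adjusted over the list alone). Of 27 NF-kB genes 23 rose (23 adjusted over the list alone). Cd83 was at 295 ± 5.11 against 71.8 ± 0.574 FPKM, and Batf and Birc3 changed by 2.30 ± 0.054 and 1.20 ± 0.039. Of 27 dark zone genes 23 fell and 1 rose (25 and 1 adjusted over the list alone), with Gcet2 at 36.9 ± 0.316 against 125 ± 1.22. Of 40 MYC targets 38 rose (39 adjusted over the list alone). Of 22 cholesterol synthesis genes 18 rose and 1 fell, as adjusted over the list alone. Of 30 mTORC1 and ATF4 genes 19 rose (20 rose and 1 fell adjusted over the list alone; 12 rose without dKO LZ replicate 2 or dKO DZ replicate 2). Examples were Gnl3, which rose by 1.19 ± 0.040, the nucleolar chaperone gene Npm1 by 0.74 ± 0.039, Cyp51 by 0.58 ± 0.049 and Asns by 1.39 ± 0.070. Of 29 G1/S genes 1 rose and 13 fell, as adjusted over the list alone; 6 fell without dKO LZ replicate 1, 8 without dKO LZ replicate 2, 6 without dKO DZ replicate 1 and 7 without dKO DZ replicate 2. The light zone list gave adjusted p = 6.72e-15 by camera and adjusted p = 0.0311 with an estimated correlation. The NF-kB list gave adjusted p = 4.11e-13 by camera and adjusted p = 0.0311 with an estimated correlation. The dark zone list gave adjusted p = 7.16e-12 by camera and adjusted p = 0.255 with an estimated correlation. The MYC list gave adjusted p = 2.28e-17 by camera and adjusted p = 0.0739 with an estimated correlation. The cholesterol list gave adjusted p = 1.04e-06 by camera and adjusted p = 0.0739 with an estimated correlation. The mTORC1 and ATF4 list gave adjusted p = 1.36e-06 by camera and adjusted p = 0.0739 with an estimated correlation. The G1/S list gave adjusted p = 0.0105 by camera and adjusted p = 0.404 with an estimated correlation. Of 21 antigen receptor response genes 9 rose and 2 fell (14 and 2 adjusted over the list alone, 6 to 13 and 1 to 2 with 1 library left out). Of 25 plasma cell genes 11 rose and 3 fell (11 and 3 adjusted over the list alone, 9 to 11 and 2 to 4 with 1 library left out). Of 20 glycolysis genes 8 rose and 0 fell (8 and 0 adjusted over the list alone, 6 to 8 and 0 with 1 library left out). Of 9 pro-survival genes 5 rose and 2 fell (5 and 2 adjusted over the list alone, 5 and 0 to 2 with 1 library left out). Of 23 survival receptor genes 11 rose and 4 fell (11 and 5 adjusted over the list alone, 9 to 11 and 2 to 5 with 1 library left out). The antigen receptor list gave adjusted p = 0.00199 by camera and adjusted p = 0.255 with an estimated correlation. The plasma cell list gave adjusted p = 0.00817 by camera and adjusted p = 0.122 with an estimated correlation. The glycolysis list gave adjusted p = 0.0105 by camera and adjusted p = 0.388 with an estimated correlation. The pro-survival list gave adjusted p = 0.0181 by camera and adjusted p = 0.348 with an estimated correlation. The survival receptor list gave adjusted p = 0.0114 by camera and adjusted p = 0.255 with an estimated correlation. The light zone and NF-kB calls held with the estimated correlation, and the other 10 lists that camera called between zones in dKO were lost. As in sKO, the direction of the light zone and dark zone lists checks the sort.

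In dKO, 3623 genes differed between zones (1915 higher and 1708 lower in LZ; limma, Benjamini-Hochberg). The count was 2267 and 2213 without dKO LZ replicates 1 and 2, and 2001 and 2090 without dKO DZ replicates 1 and 2. Genes called in both genotypes, from separate libraries, numbered 1177 higher in LZ (290.4 expected of independent lists) and 1215 lower (274.1 expected). Only 8 were called in opposite directions (566.4 expected). These lists also share each gene's variance from the same fit, so the expected numbers are again a loose guide. The zone changes of sKO and dKO correlated at 0.860 across 7775 genes. Of the 3312 genes called in sKO, 3194 (96.4%) had the same sign in dKO, and the median ratio of the dKO to the sKO change was 0.915. That ratio is likewise biased downward by choosing genes called in sKO.

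**Figure D4:**
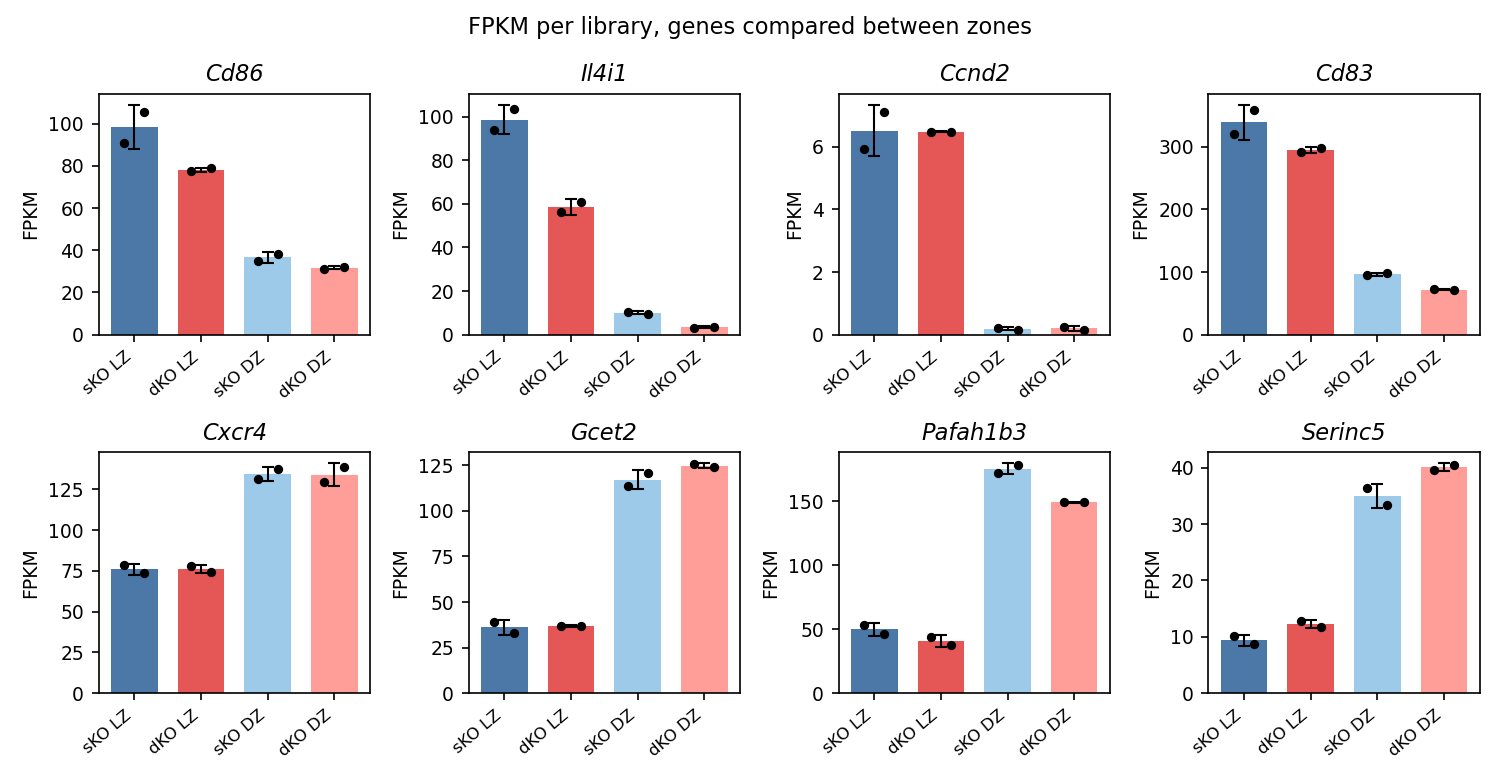
FPKM of 8 genes in the 4 groups, with bars for the mean, error bars for the SD (n = 2) and points for the 2 libraries. Cd86, Il4i1, Ccnd2 and Cd83 were higher in LZ, and Cxcr4, Gcet2, Pafah1b3 and Serinc5 higher in DZ, in both genotypes; Cd86 and Cxcr4 were used for the sort.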

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

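The fit without small RNA genes was chosen only after the interaction calls were seen. The genotype effect differed between zones in 3 genes by the interaction test, all microRNA genes, and each was listed at 0 FPKM in at least 4 of the 8 libraries. Mir194-1 was at 261 and 299.7 FPKM in the sKO DZ libraries and 0 in the other 6 (interaction 8.13 ± 0.12, adjusted p = 1.75e-06). Mir1943 was at 152 and 175 in sKO DZ and 0 elsewhere (7.36 ± 0.12, adjusted p = 1.98e-06). Mir3112 was at 119 and 124 in dKO LZ, 161 and 92.2 in sKO DZ and 0 elsewhere (13.88 ± 0.32, adjusted p = 1.15e-05). FPKM of a very short gene turns few reads into a high value. Instability of such values fits: the median replicate difference of small RNA genes was 13.28 times that of other genes (1.03 against 0.077 on the log2 scale), a test planned before the result was seen. In 231 of 636 replicate pairs of small RNA genes (36.32%) 1 library was under 0.01 FPKM and the other at least 1, against 34 of 41804 pairs (0.08%) of other genes. A true zone-specific effect of Bach2 loss on these microRNA genes stays open and untested. Replicates were alike in Mir194-1 and Mir1943, but Mir3112 differed between the sKO DZ libraries (161 and 92.2 FPKM). Mir194-1 and Mir1943 were lower in the deeper of the sKO DZ libraries (relative depth 1.625 in replicate 1 and 1.417 in replicate 2). The same few reads in each library would give such values, so the likeness of these replicates is no evidence of an effect.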

How the results depend on the processing

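The fits without small RNA genes and without both sKO replicate 1 libraries were chosen after the data were seen. Other pseudocounts, filters, scalings and variance priors kept each genotype and zone count within 1.5 times its value. Fitting only the groups compared, with fewer degrees of freedom, gave 2177 genes in place of 3299 for genotype in LZ, 649 in place of 1258 in DZ and 1678 in place of 3312 for zone in sKO. Without both sKO replicate 1 libraries the DZ genotype count was 501, the interaction count 15 in place of 3, and calls were gained by Myc in LZ (adjusted p = 0.00701), in DZ (0.925, adjusted p = 0.0118) and for zone in sKO (adjusted p = 0.00318), and by Cd86 in DZ (-0.268, adjusted p = 0.0463). Bcl6 in LZ gained one with upper quartile scaling (-0.157) and quantile normalization (-0.197). Myc for zone in sKO, at an adjusted p of 0.0517, passed in 7 alternatives other than leaving out 1 library (0.00318 to 0.0496) and without sKO DZ replicate 1 (0.00545). The interaction count was 5 with no filter and 0 without small RNA genes. Leaving out 1 library at a time gave 1703 to 3140 genes for genotype in LZ, 105 to 1339 in DZ, 2001 to 3053 for zone in sKO, 2001 to 3856 for zone in dKO, 3 to 6 for the interaction and 2726 to 3765 over both zones (3942 with all libraries). The group left with a lone library is assumed to vary like the others.

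Of 26 lists tested, 14 were called for genotype in LZ, 16 in DZ, 15 for zone in sKO, 12 in dKO, 8 for the interaction and 17 over both zones. With an estimated correlation these counts were 0, 0, 2, 2, 0 and 0, and for the interaction 5 with quantile normalization and 5 with fry. Leaving out 1 library gave 14 to 17 lists in LZ, 14 to 17 in DZ, 12 to 15 and 12 to 14 between zones, 7 to 12 for the interaction and 14 to 17 over both zones. The list of AP-1 and MAF factors turned from lower to higher in DZ without both sKO replicate 1 libraries (adjusted p = 0.0424), and that of cytosolic ribosomal proteins to lower for zone in dKO with quantile normalization (0.00572). Uncalled values near 0 changed sign: Cxcr4 in LZ (-0.057 with upper quartile scaling, -0.066 with quantile normalization and -0.042 to 0.047 without 1 library), Cxcr4 in DZ (-0.055 to 0.047), Ccr6 in DZ (-0.12 to 0.045) and Bcl6 between zones in sKO (-0.028 without both sKO replicate 1 libraries, -0.052 to 0.065 without 1 library). The cause was not tested. Of 3803 values of named genes under the alternatives, 3656 kept their direction and side of the threshold, 120 lost and 16 gained the call, and 11 changed sign.

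No label says that the numbers 1 and 2 pair libraries. With the replicate number as a block the count was 2994 for genotype in LZ, 881 in DZ and 3641 over both zones. The block was 1 term shared by both genotypes. It therefore cannot take up a replicate difference that LZ and DZ share within a single genotype, and such pairing was not modelled. Replicate differences correlated at 0.155 between sKO LZ and sKO DZ, 0.277 between dKO LZ and dKO DZ, 0.189 between the LZ groups, 0.076 between the DZ groups, and 0.048 and -0.008 for the rest. The planned tests on counts were not run, since the file holds none.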

Other observations

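The tests of depth, shared handling, heat shock and myeloid cells below were chosen only after the result was seen. Of 9 pro-survival genes of the BCL2 and inhibitor of apoptosis families, 1 rose and 1 fell (1 and 1 adjusted over the list alone, 0 to 1 and 1 to 5 with 1 library left out) in LZ. In DZ 0 rose and 3 fell (0 and 4 adjusted over the list alone, 0 and 0 to 3 with 1 library left out). Of 12 pro-apoptotic genes 1 rose and 3 fell (1 and 3 adjusted over the list alone, 1 and 3 with 1 library left out) in LZ. In DZ 1 rose and 1 fell (1 and 1 adjusted over the list alone, 1 and 0 to 1 with 1 library left out). In LZ camera gave adjusted p = 0.0654 for the pro-survival list, 0.00243 without sKO LZ replicate 1, where 5 genes fell, and 0.0489 without dKO LZ replicate 2. The 3 lower pro-survival genes in DZ, Bcl2a1a, Bcl2a1d and Bcl2a1b, are near-identical copies that can share reads. In DZ camera gave adjusted p = 0.0388, lost without dKO LZ replicate 1 (0.0518), dKO LZ replicate 2 (0.0518), sKO DZ replicate 1 (0.0788), sKO DZ replicate 2 (0.0594), dKO DZ replicate 1 (0.0953), and adjusted p = 0.456 with an estimated correlation. Of 13 quiescence genes in DZ, 0 rose and 4 fell (1 and 6 adjusted over the list alone), and fewer fell in some fits with 1 library left out. The p27 gene Cdkn1b changed by -0.74 ± 0.10, a call lost without sKO DZ replicate 1 or dKO DZ replicate 1. For the list, camera gave adjusted p = 0.013, and adjusted p = 0.179 with an estimated correlation. Of 11 interferon response genes 1 rose and 3 fell (2 and 4 adjusted over the list alone, 0 to 1 and 3 to 4 with 1 library left out) in LZ. In DZ 1 rose and 3 fell (2 and 3 adjusted over the list alone, 0 and 0 to 3 with 1 library left out). The interferon regulator gene Irf7 fell in LZ from 14.7 ± 0.736 to 8.68 ± 0.172 FPKM (-0.70 ± 0.065, adjusted p = 0.00133) and camera gave adjusted p = 0.135 and 0.167 for the list.

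Of 21 antigen receptor response genes 2 rose and 3 fell (2 and 3 adjusted over the list alone, 1 to 3 and 1 to 4 with 1 library left out) in LZ. In DZ 2 rose and 1 fell (2 and 3 adjusted over the list alone, 1 to 2 and 1 to 3 with 1 library left out). Of the MAP kinase phosphatase genes, Dusp5 changed by 1.20 ± 0.070 in LZ and 1.03 ± 0.070 in DZ, and Dusp4 by -0.71 ± 0.072 and -0.93 ± 0.072 (camera adjusted p = 0.287 and 0.123). The camera p in DZ was 0.00866 without sKO DZ replicate 2. Of 11 AP-1 and MAF factors 4 rose and 0 fell (4 and 0 adjusted over the list alone, 1 to 4 and 0 to 1 with 1 library left out) in LZ. Their median there was 0.13 (-0.030 to 0.40 with 1 library left out) and their mean -0.005. In DZ 1 rose and 1 fell (1 and 1 adjusted over the list alone, 0 to 1 and 0 to 1 with 1 library left out). Camera gave adjusted p = 0.287 in LZ, 0.028 without sKO LZ replicate 1, and 0.846 in DZ. Of 27 dark zone genes 10 rose and 1 fell (10 and 2 adjusted over the list alone, 3 to 15 and 1 to 3 with 1 library left out) in LZ. In DZ 2 rose and 1 fell (3 and 1 adjusted over the list alone, 0 to 5 and 0 to 1 with 1 library left out). Camera gave adjusted p = 0.0583 in LZ, 0.00149 and 0.0393 without sKO LZ replicate 1 and dKO LZ replicate 2. In DZ it gave 0.076, and 0.0178 and 0.0178 without sKO LZ replicates 1 and 2. Of 11 heat shock and dissociation genes 4 rose and 0 fell (4 and 0 adjusted over the list alone, 4 to 5 and 0 with 1 library left out) in LZ. In DZ 3 rose and 0 fell (5 and 0 adjusted over the list alone, 0 to 4 and 0 with 1 library left out). The chaperone gene Hsp90aa1 rose in both zones (0.53 ± 0.044 and 0.36 ± 0.044), but its DZ call was lost without dKO DZ replicate 1 or replicate 2. Camera gave adjusted p = 0.0576 in LZ, 0.00188 and 0.0489 without sKO LZ replicate 1 and dKO LZ replicate 2. In DZ it gave 0.0388, lost without sKO DZ replicate 2 (0.302), dKO DZ replicate 1 (0.0727), and adjusted p = 0.574 with an estimated correlation.

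Markers of other cells were mostly below the filter. Of 14 T cell markers 3 were tested and none was called between genotypes in either zone, alone or over all genes (camera adjusted p = 0.851 and 0.747). Between zones, however, 2 of these 3 were higher in LZ over DZ in both genotypes, in every fit without 1 library and adjusted over the list alone. They were the kinase gene Lck (0.68 ± 0.060 in sKO and 0.89 ± 0.060 in dKO) and the adaptor gene Lat (0.99 ± 0.11 and 0.87 ± 0.11). Camera gave adjusted p = 0.0343 in sKO, lost without sKO LZ replicate 1 (0.0565), sKO DZ replicate 2 (0.0885), and adjusted p = 0.197 with an estimated correlation. In dKO it gave 0.0743, and 0.0317 without dKO DZ replicate 2. The other 11 T cell markers were below the filter, and whether T cells carried over into the LZ sort was not tested. Of 21 myeloid markers 9 were tested, and 1 rose and 0 fell (1 and 1 adjusted over the list alone, 1 and 0 to 1 with 1 library left out) in DZ (0.851). Of 10 erythroid and platelet markers 3 were tested, and 0 rose and 1 fell (0 and 1 adjusted over the list alone, 0 to 2 and 1 with 1 library left out) in LZ. The list median there was 0.43, -0.36 to 1.22 with 1 library left out, and camera gave adjusted p = 0.663. In DZ 0 rose and 0 fell (0 and 0 adjusted over the list alone, 0 and 0 with 1 library left out) (0.812). Of 10 NK and innate markers 1 was tested, at -0.21 in LZ (-0.41 to 0.001 with 1 library left out) and -0.52 in DZ. It had 0 calls over all genes. Over the list alone it was lower in DZ at a p under 0.05 (limma), which is unadjusted, as the list holds 1 tested gene. Of 12 stromal markers 2 were tested, and 0 rose and 1 fell (0 and 1 adjusted over the list alone, 0 and 1 with 1 library left out) in LZ. In DZ 0 rose and 1 fell (1 and 1 adjusted over the list alone, 0 and 0 to 1 with 1 library left out). None of the 12 listed immunoglobulin constant genes was in the file, and 17 listed symbols in all were absent.

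The MYC target list was higher in dKO in both zones, and technical explanations were weighed for it. After removal of linear trends on transcript length, GC content and expression, its median in LZ was 0.52 (95% interval over members 0.474 to 0.571; 0.54 before), and all 40 members had length and GC values. Under quantile normalization, its median less that of all genes was 0.487 (0.429 to 0.521). In DZ, where dKO libraries were 0.971 times as deep as sKO libraries, against 1.053 times in LZ, its median was 0.371 (0.32 to 0.419), so depth, length and scaling each do not account for it. The 8 libraries were split into 4 and 4 in 34 ways that could be fitted with a zone term. Of these 1, the real one, called 3699 genes for genotype over both zones, and the highest of the others was 4. Each other split had both genotypes on both sides, so the genotype difference added to its residual spread and held its count down. The splits therefore cannot decide whether a chance difference between pools gave that number of genes. The MYC list was not tested under the splits. An effect of Bach2 loss remains a hypothesis that is consistent with these values, and a difference between the mice or sorts of each genotype, which the design does not separate from it, stays open.

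Fos and Jun, immediate early genes, were high in both sKO replicate 1 libraries: the ratio of replicate 1 to 2 was 4.25 in LZ and 3.32 in DZ for Fos and 3.95 and 2.88 for Jun. Among 7775 genes, 9 were over 1 on the log2 scale higher in replicate 1 of sKO in both zones (Rgs1, Fosb, Dusp1, Fos, Ppp1r15a, Jun, Klf2, Rhob and Zfp36), against 1 in dKO. Over 37 members of the AP-1, antigen receptor and heat shock lists other than Fos and Jun, which were left out once a first form of the test had been seen, the replicate differences of sKO correlated between zones at 0.803 (0.409 to 0.948), against 0.215 in dKO, so shared handling of replicate 1 is possible but cannot be told apart from a difference between the mice, as the labels name no batch. Heat shock genes had a median difference of 0.103 (0.053 to 0.526) in LZ and 0.048 (-0.029 to 0.219) in DZ, the DZ value being made the deciding one after both were seen, and 3 of 3 of the myeloid genes S100a8, S100a9 and Lyz2 were lower in replicate 1 of sKO LZ. The DZ value goes against heat shock, while the LZ interval, which reached 0.526, is too wide to decide. The 3 myeloid genes go against myeloid cells in sKO LZ replicate 1, and sKO DZ was not part of that test. No biological explanation was tested.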
